A study of Homo sapiens with 6 samples.

How the data were processed

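RNA sequencing was carried out on 6 libraries from A673 cells, 3 with control siRNA and 3 with an siRNA against RREB1. Per the labels' protocols, libraries were made with a strand-specific Illumina TruSeq kit for messenger RNA. Per the submitters' processing notes, STAR 2.6.1a and DESeq2 1.34.0 were used and the genome build was hg19. The role of each tool, the read counter and the gene annotation are not given in the sources used here. The authors deposited 1 table of values per Ensembl gene, which its name calls raw counts, and 1 table that pairs each gene identifier with a symbol.

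Groups were taken from the sample titles before the data were examined. The count table has 6 columns of per-library values, and the names of all 6 match no title, description or other label. The values in these columns were looked at only to identify their unit, and no result given here was computed from them. Of the count table, only the column names and gene identifiers were used for the results. Gene symbols came from the symbol table and gene types from GENCODE release 29. The comparison planned before the data were examined was a quasi-likelihood test on the counts, siRREB1 against siCT. It was not run, nor was any other fit. The rule fixed for naming genes by the size of their change was likewise not applied. The genes named here are the target of the siRNA, examples from fixed lists and 2 further kinds of list member. These are the members that were not found and those whose symbol is carried by several identifiers. None of the genes was chosen on any expression value.

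The gene identifiers were compared between both tables, and gene types were looked up by identifier, without version numbers, in GENCODE release 29. That release is on GRCh38, while the counts were made on hg19, so it was used for gene types only and no coordinates are given. Members of the 27 gene lists were looked up by their current symbol and, where one had been recorded with the list, by an older symbol. The lookups were made with Python 3.11.15. The depth of each library, and the precision it gives, was not analysed here.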

Results

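The series measured polyadenylated RNA in A673 cells, an established human Ewing sarcoma cell line, after transfection with a small interfering RNA (siRNA). RREB1, the gene targeted by the siRNA, encodes a zinc finger transcription factor that binds Ras-responsive DNA elements. Per the labels, 3 libraries came from cells given a control siRNA (siCT) and 3 from cells given 1 siRNA against RREB1 (siRREB1). Both siRNAs were used at 50 nM, and RNA was taken 72 h after transfection. Each group had 1 library in each of 3 numbered sets. The labels do not say whether a set was a separate culture, day or passage.

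The design implies 1 comparison, siRREB1 against siCT, which asks which transcripts differ when RREB1 is knocked down in these cells. That comparison could not be made here. The deposited count table has 6 columns of values, and all 6 carry code names that occur in none of the labels used here. No column could therefore be assigned to a library, a group or a set by its name. Assigning columns by their order, or by how many RREB1 reads they hold, would have rested on a guess or on the outcome itself, and neither was done. For this reason no expression value, sequencing depth, fold change or test is reported, for RREB1 or for any other gene, and nothing is stated about whether the knockdown lowered RREB1 RNA.

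What could be described is the set of genes over which the counts were made. The table covers 57820 Ensembl gene identifiers, each listed once, and the deposited symbol table lists the same identifiers in the same order. RREB1 is present as 1 identifier, ENSG00000124782, which GENCODE release 29 classes as protein-coding. Of the identifiers, 52338 are also in GENCODE release 29. Among these, 19263 are protein-coding genes, 9749 are processed pseudogenes, 6576 are long intergenic non-coding RNAs and 5097 are antisense genes. The remaining 5482 identifiers are not in that release.

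The gene lists fixed before the data were examined are almost fully represented. Of 587 distinct genes in 27 lists, 585 have a symbol in the table. All 38 genes listed as activated by EWSR1-FLI1, the fusion transcription factor of Ewing sarcoma, are present, among them NR0B1, NKX2-2 and STEAP1. All 30 genes listed as repressed by the fusion are present, among them LOX, TGFBR2 and IGFBP3. The 29 TGF-beta and epithelial-mesenchymal transition genes, the 22 MAPK output genes, the 30 genes of G1/S and DNA replication and the 30 genes of G2/M and mitosis are also complete. TIGAR, in the p53 target list, and PECAM1, in the endothelial marker list, were not found under the symbols used here. No older symbol had been recorded for either gene, and neither was looked up by identifier. Whether they were counted under another symbol is therefore not known. Presence in the table says that a gene was counted, not that it was expressed. The lookup used gene symbols alone, so the coverage of the lists describes the gene annotation, not the A673 cells or the siRNA.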

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

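No paired analysis was possible because the count columns could not be matched to libraries or sets, so no model was fitted. For the same reason none of the alternatives planned before the data were examined was run (other normalizations, tests and low-count filters, the set number as a block, libraries or sets left out, other gene set tests, and a test against a minimum fold change). The number of list genes present in the table was recomputed in 2 ways chosen after seeing the data. It was 585 with current or older symbols, 579 with current symbols only and 582 when genes whose symbol is carried by several identifiers were left out. The genes left out in the last case are NDUFB8, SDHD and TUBB3. Of all 55765 symbols in the table, 289 are carried by several identifiers.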
